A study of Tetranychus urticae with 4 samples.

How the data were processed

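RNA sequencing libraries were made from adult females of the London strain of the spider mite Tetranychus urticae, a laboratory strain of a plant-feeding mite. There were 3 whole-body libraries, each from 100 intact females, and 1 library from the dissected proterosoma of 250 females. The proterosoma is the front part of the mite body, which carries the mouthparts and holds the salivary glands. Libraries were strand-specific, per the labels' protocols. The sources used here do not say whether the 3 whole-body libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

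The deposited gene table holds raw counts of reads per gene. STAR 2.5.0b, HTSeq 0.6.0 and DESeq2 1.6.3 are named in the submitters' processing notes. The genome build, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Near-identical gene copies could therefore share or lose reads, and reads of overlapping or antisense genes may not have been told apart. The authors also deposited a table of their own comparison with DESeq2 column names: a mean normalised signal per gene, log2 fold changes with their errors, the test score, p-values and adjusted p-values. The header of that table does not say which group is the numerator. For all genes with an absolute deposited log2 fold of at least 1, the sign was that of proterosoma over whole body in the counts (100%). The deposited mean signal matched the mean of counts divided by median-of-ratios size factors to within 0.1% for 100% of the genes. Every sample column of the count table was matched to its sample by title, and the number of columns left unused was 0.

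The table listed 18020 gene identifiers and held no summary lines for unassigned reads. No count was present in any library for 2143 of them. Total counts were 23647775, 12356237 and 11630954 for whole-body replicates 1, 2 and 3 and 19667380 for the proterosoma library. A count of 0, which allows up to 3 counts, limits a gene to 0.127, 0.243, 0.258 and 0.153 CPM (counts scaled to a common library size) in these libraries, in the same order. Such limits cover counting error only, since the reads carry no molecular identifiers. No pair of whole-body libraries was a repeat of the same library: the chi-square statistic per degree of freedom over genes was 15.5, 27.9 and 16.5 for the 3 pairs.

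Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, edgeR's expression filter by group) in R 4.3.3. All 4 libraries entered 1 model with body part as its only term. Only whole bodies were replicated, so the spread came from them (2 residual degrees of freedom, with 3.82 prior degrees of freedom), and the lone proterosoma library was assumed to vary like a whole-body library. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and counted again with a fold of at least 2. CPM values used TMM-scaled library sizes unless stated otherwise. The standard error of a log2 fold was taken as the fold divided by the square root of its F statistic. The same test set each whole-body library against the other whole-body libraries, with the proterosoma library left out.

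The test was tried on simulated counts built on the whole-body means, the spread and the library sizes of this comparison. There were 12555 genes tested and 200 genes changed in the proterosoma arm. The test recovered 22% of the genes changed 1.5-fold, 72% of those changed 2-fold, 96% of those changed 4-fold and 98% of those changed 8-fold, with 24 calls among unchanged genes. Apart from the changed genes, the simulated proterosoma library had the profile and spread of a whole body. The trial therefore covered neither the scaling when most genes differ nor the assumption that the lone library varies like whole bodies.

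Alternatives fixed before the data were examined were 3 other scalings (DESeq2 size factors, upper quartile, library size alone), 2 other filters (at least 1 count; a mean count of at least 50), the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), a robust fit, an adjusted p of 0.01, a test against a 2-fold change (glmTreat), and the omission of each whole-body library. The rule for named genes was also fixed then. None of the 18020 identifiers was found in the reference table of gene names, and the deposited files do not pair identifiers with names. The rule then allows 4 identifiers: in each direction the gene with the largest fold among those with a mean of at least 10 CPM, and the most abundant gene, each called with at least a 2-fold change and with the proterosoma value outside the range of the whole-body libraries. Gene lists fixed by product name could not be matched to identifiers, and lists fixed by identifier could not be checked against an annotation, so list tests were not run. Shuffles of neighbouring genes were drawn over all tested genes and within 10 classes of mean expression. Shuffles and interval calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.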

Results

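Gene expression was compared between the dissected front body (proterosoma) and the intact body of adult female spider mites. The aim was to find genes with enriched expression in the salivary glands, which lie in the front body. No identifier could be matched to a gene name. The genes found higher were therefore not assigned to the salivary glands or to any other front-body tissue. Reads were counted for 14969, 14458 and 14407 genes in whole-body replicates 1, 2 and 3 and for 14594 genes in the single proterosoma library. The 10 most abundant genes took 17.9%, 21.1% and 22.4% of the reads of the whole-body libraries and 16.6% of the proterosoma reads. The 100 most abundant genes took 41.3% of the proterosoma reads and at most 34.1% of the reads of a whole-body library. Correlations of log2 CPM across genes, which are not independent replicates, were 0.986 to 0.991 between whole-body libraries and 0.649 to 0.657 between these and the proterosoma library.

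The front body and the whole body differed in most of the genes they expressed. Of 13278 genes tested, 5449 were higher and 5363 lower in the proterosoma library, and 2466 were not called (edgeR quasi-likelihood test, adjusted p under 0.05). Of the called genes, 4192 were at least 2-fold higher and 3981 at least 2-fold lower. For all 8173 of these the proterosoma value lay outside the range of the 3 whole-body values, which the choice of genes all but ensures. Without each whole-body library in turn, 7641 of the 8173 were called again, in the same direction and with at least a 2-fold change, in all 3 fits. Because there was 1 proterosoma library, no difference has a replicate check on that side. Most genes differed, so the split depends on the scaling: 50.4% of the calls were higher with TMM and 37.5% with library size alone, which moved the log2 fold by a median of -0.57.

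Genes enriched in the front body took most of its reads: the 4192 genes at least 2-fold higher held 68.2% of the proterosoma reads and 11.5% ± 0.463 (SD, n = 3) of the whole-body reads. The 1809 genes at least 8-fold higher held 48.8% of the proterosoma reads and 2.94% ± 0.222 (SD, n = 3) of the whole-body reads. Among them, the 1045 genes at least 16-fold higher held 39.6% of the proterosoma reads and 1.79% ± 0.196 (SD, n = 3) of the whole-body reads. The 3981 genes at least 2-fold lower held 7.77% of the proterosoma reads and 52.6% ± 1.63 (SD, n = 3) of the whole-body reads. Among them, the 1313 genes at least 8-fold lower held 0.452% of the proterosoma reads and 13.8% ± 0.186 (SD, n = 3) of the whole-body reads. The 2466 genes that were not called held 10.1% of the proterosoma reads and 14.8% ± 0.652 (SD, n = 3) of the whole-body reads. These shares describe genes chosen by their fold in these same libraries.

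**Figure D1:**
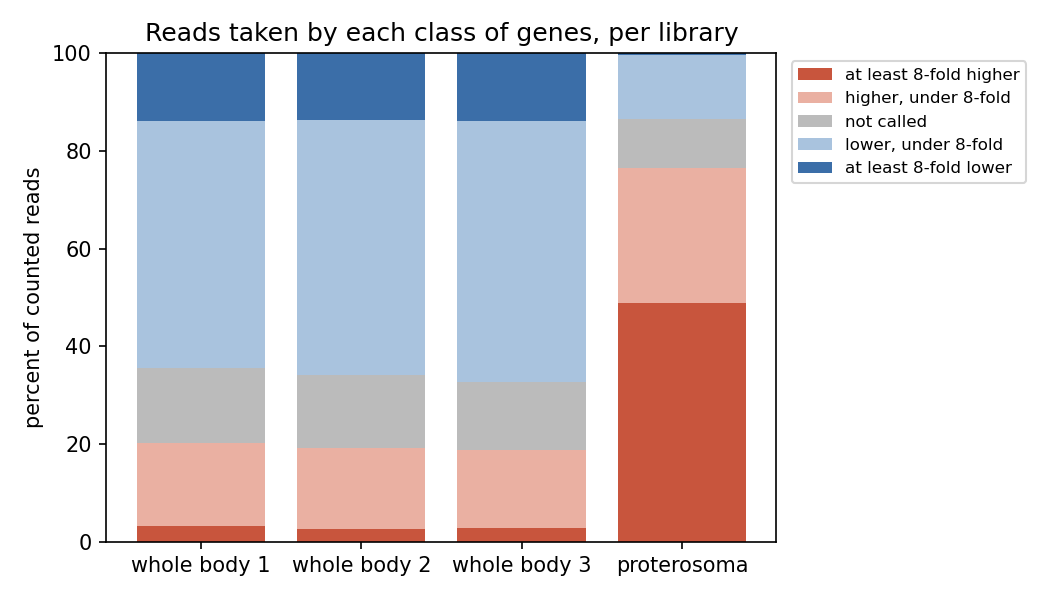
Stacked bars give the percent of counted reads (vertical axis) that each class of genes took in each of the 4 libraries (horizontal axis), with classes set by the called fold of proterosoma over whole body; genes outside the test are left out. Genes at least 8-fold higher took 48.8% of the proterosoma reads against 2.74% to 3.18% in the whole-body libraries.

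The most abundant transcripts of the front and the whole body overlapped in part. Of the 100 most abundant genes of the proterosoma library, 21 were also among the 100 most abundant of the whole body. At least 2-fold higher in the proterosoma library were 91 of its own top 100 genes, and at least 2-fold lower were 5. Of the whole-body top 100, 58 were at least 2-fold lower and 12 at least 2-fold higher in the proterosoma library. The whole-body top 100 genes held 32.2% ± 2.04 (SD, n = 3) of the whole-body reads and 20.9% of the proterosoma reads. The proterosoma top 100 genes held 41.3% of the proterosoma reads and 22.2% ± 1.81 (SD, n = 3) of the whole-body reads.

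The gene tetur39g00530 was the most abundant gene of the proterosoma library among those that rose. It reached 53400 CPM there and 1390 ± 218 CPM in whole bodies (SD, n = 3), a 38.5-fold difference with a log2 standard error of 0.22 (edgeR adjusted p = 4.59e-06). It alone took 3.97% of the proterosoma reads and 0.154% ± 0.0288 (SD, n = 3) of the whole-body reads. The gene with the largest rise was tetur03g08450, at 2400 CPM in the proterosoma library and 1.99 ± 0.524 CPM in whole bodies (SD, n = 3). Its log2 fold was 10.17 with a standard error of 0.24 (edgeR adjusted p = 1.19e-06), from 35080 proterosoma reads against 70, 22 and 22 whole-body reads. Whether the body part alone can give so large a fold is weighed under the other observations.

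The gene tetur03g09300 was the most abundant whole-body gene among those that fell. It stood at 66900 ± 10800 CPM in whole bodies (SD, n = 3) and at 16100 CPM in the proterosoma library, a log2 fold of -2.05 with a standard error of 0.30 (edgeR adjusted p = 9.99e-04). It took 7.35% ± 0.981 (SD, n = 3) of the whole-body reads and remained at 1.20% of the proterosoma reads. The gene with the largest fitted fall, tetur03g05730, had 0 reads in the proterosoma library, against 824, 377 and 313 in whole-body replicates 1, 2 and 3. Its whole-body level was 27.8 ± 2.71 CPM (SD, n = 3). Against the 0.205 CPM that 3 reads in the proterosoma library would give, it was at least 136-fold lower (edgeR adjusted p = 5.57e-06).

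**Figure D2:**
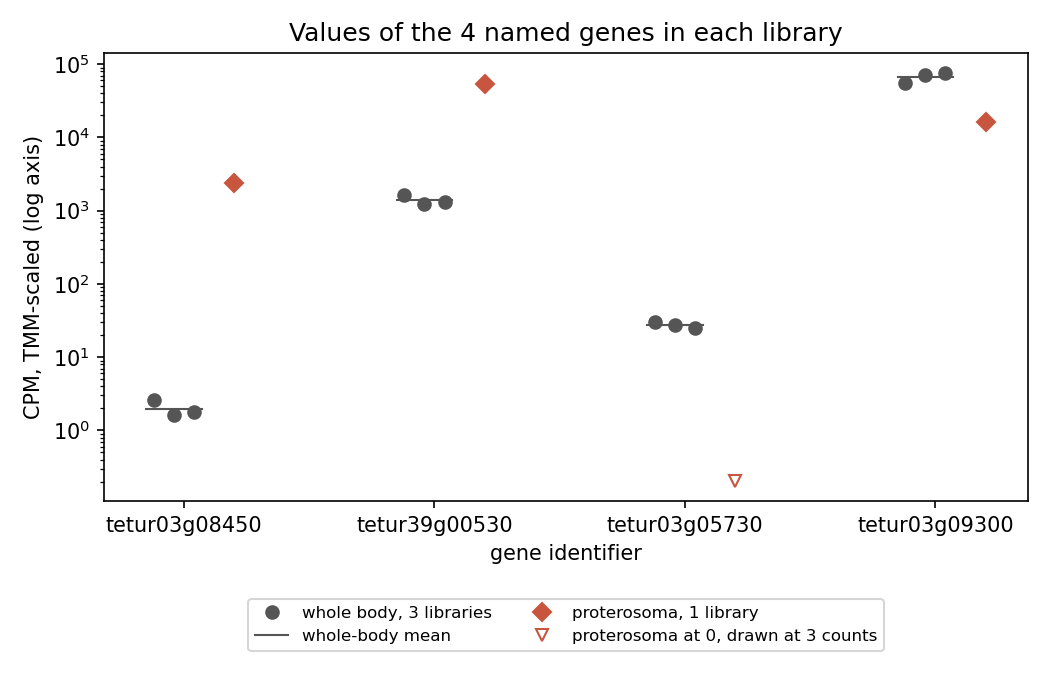
The TMM-scaled CPM of the 4 named genes (log vertical axis) is shown for each whole-body library (circles, with their mean as a line) and for the proterosoma library (diamond); the open triangle marks a count of 0, drawn at the level of 3 counts. By the rule that chose the genes, each proterosoma value lies outside the 3 whole-body values, as for tetur39g00530 at 53400 CPM against 1230 to 1640 CPM.

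Fold changes were spread differently in the 2 directions. Among the 8243 genes with a mean of at least 10 CPM, the number of genes per 0.5 log2 units fell from 957 just above 0 to 139 at log2 folds of 3 to 3.5. It then stayed level, at 150, 141 and 133 genes in the next intervals up to a log2 fold of 5, and dropped to 83, 76, 29 and 13 genes in the intervals up to 7. On the lower side the numbers declined from 156 genes between -3.5 and -3 to 119, 94 and 71 genes in the next intervals down to -5. Beyond that the decline was not steady, with 72, 46, 30 and 44 genes in the intervals down to -7. No test of this shape was made, and counts of genes in neighbouring intervals carry counting error. The mean of at least 10 CPM is taken over 4 libraries, 3 of them whole body, so the filter does not treat the 2 directions alike.

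**Figure D3:**
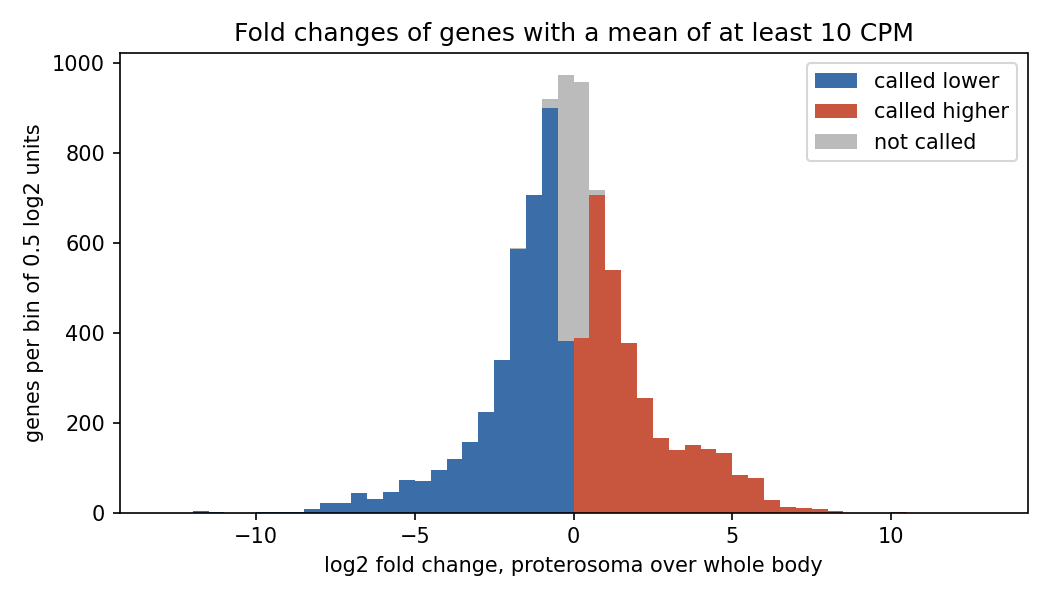
The histogram gives the number of genes (vertical axis) per 0.5 log2 units of the fold of proterosoma over whole body (horizontal axis) for 8243 genes with a mean of at least 10 CPM, coloured by whether the gene was called higher, lower or not. A shoulder of 133 to 150 genes per interval lies between log2 folds of 3 and 5.

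Some genes had reads on 1 side of the comparison only. No read in any whole-body library and at least 10 reads in the proterosoma library were found for 35 genes, with a median of 14 and a maximum of 441 proterosoma reads. No proterosoma read and at least 10 reads in every whole-body library were found for 153 genes. Of the genes with no proterosoma read, 11 had a mean of at least 10 CPM in whole bodies, scaled by library size alone. With a count of 0, up to 0.153 CPM in the proterosoma library is not excluded, so these genes were below detection at this depth. For the 35 genes without whole-body reads, the limits were 0.127, 0.243 and 0.258 CPM in whole-body replicates 1, 2 and 3. A lack of whole-body reads is no evidence of absence there, since an intact body contains its front body.

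The 3 whole-body libraries differed far less from each other than from the proterosoma library. Set against the other whole-body libraries by the same edgeR test over 12228 genes, replicate 1 gave 0 calls, replicate 2 gave 27 higher and 161 lower genes, and replicate 3 gave 1 higher and 0 lower genes. At an unadjusted p under 0.05 the numbers were 238, 785 and 1095 genes. Each of these tests takes its spread from 2 libraries (1 residual degree of freedom). The DESeq2 Wald test called 0, 84 and 27 genes for replicates 1, 2 and 3. The proterosoma library against all 3 gave 10812 calls.

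The authors' deposited table compares the same libraries over the 15877 genes with at least 1 count. In the authors' deposited table, the genes higher in the proterosoma library numbered 4878 and the genes lower there 4901 at an adjusted p under 0.05, and 3975 and 3797 of them differed by at least 2-fold. Of the edgeR calls, 4801 higher and 4875 lower genes were also called in the authors' deposited table, 1136 were not, and 0 were called in the opposite direction. The log2 folds of the 2 fits had a Pearson correlation of 0.992 across 13278 genes, which are not independent replicates. The authors' deposited table gave a log2 fold of 5.24 for tetur39g00530 with an error of 0.20, 10.11 for tetur03g08450 with an error of 0.23, and -2.06 for tetur03g09300 with an error of 0.21. For tetur03g05730, which had no proterosoma read, the authors' deposited table gave -8.87 with an error of 1.34.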

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

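Tests of the whole-body libraries by DESeq2, by library size alone and after thinning were chosen after seeing the data. Of 125 values under alternatives, 119 kept their direction and their side of the threshold, or stayed within 1.5 times the main count. The share of calls that were higher was judged by its difference in percentage points instead, and library size alone counted as a move. All 52 recomputed log2 folds of the 4 named genes were among them. Under library size alone the share of calls that were higher was 37.5%, against 50.4%, since the proterosoma library has a TMM factor of 0.744 and the whole-body libraries 1.07 to 1.14. That scaling called 80 of the 10812 genes in the opposite direction, but 0 of those with at least a 2-fold change, and 7072 of the 8173 genes with at least a 2-fold change (3262 higher and 3810 lower) kept call, direction and size under all 4 scalings. Testing against a 2-fold change with glmTreat left 3317 lower genes, because that test asks for more than a difference from 0. For whole-body replicate 2 against the others, 188 calls became 84 with the DESeq2 Wald test and a median of 121 with the whole-body libraries thinned to 1 depth; for replicate 3, 1 call became 27 with DESeq2 and 0 with library size alone, and the cause was not tested. No paired analysis was possible because the proterosoma library carries no replicate number and has no replicates. Tests of gene lists under other scalings, filters and correlations were not run, since no list could be matched to the identifiers. The expression filter left 2599 genes with at least 1 count untested, and among tested genes the simulation recovered 22% of 1.5-fold and 72% of 2-fold changes; the effect of depth on the comparison of body parts was not tested by thinning reads.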

Other observations

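The edgeR test of each whole-body library against the others was set before the data were examined; the other tests in this part were chosen after the data were seen.

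Genes enriched in or depleted from the front body tended to sit side by side. Identifiers were ordered by the scaffold and serial number they contain, an order that was not checked against an annotation. Of 10870 neighbouring pairs of tested genes, 652 were both called at least 4-fold higher, and 487 pairs were both at least 4-fold lower, where shuffles of the genes among genes of like mean expression gave 305 on average. Runs of at least 3 adjacent genes were compared with 100 shuffles over all tested genes, not matched on expression. The runs numbered 121 for the higher genes, against at most 84 in a shuffle, and 86 for the lower genes, against at most 53. The longest higher run held 9 genes on scaffold 57 and the longest lower run 12 genes on scaffold 11.

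Chance placement and the expression level of neighbours were weighed for the side-by-side higher genes. The 652 pairs exceeded the 501 pairs at the upper end of the 95% range of shuffles over all tested genes (permutation p = 0.0001, the smallest that 10000 shuffles can give), which argues against chance. They were 1.43 times the mean of shuffles among genes of like mean expression, which argues against level alone; over all called higher genes, with no fold minimum, the excess was smaller, at 1999 pairs against a mean of 1816 in such shuffles. Pairs 5 places apart numbered 464, under the upper end of that range for the first kind of shuffle (472) and over it for the second (459), so read sharing or overlap between next neighbours cannot be told apart from wider clusters; without sequences, the similarity of adjacent copies was not tested. For the lower genes, the 305 pairs 5 places apart lay under both upper ends (320 and 317), so no excess was detected at that distance, as read sharing or overlap of next neighbours would give; that and shared regulation of duplicated genes stay open.

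Folds far above the shoulder bear on the share of the front body in the whole. An intact body contains its front body, so, with both in the same state, no gene can be enriched by more than the inverse of the front body's share of the body's messenger RNA. On library-size scaling, 452 genes with at least 10 CPM in the proterosoma library were over 16-fold higher, which would require a share under 6.25%. Over 64-fold higher were 45 genes, which would require a share under 1.56% if their folds are taken at face value. Those 45 genes took 2.32% of the proterosoma reads and 0.022% of the whole-body reads.

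Counting noise did not account for the group as a whole: the lower exact 95% Poisson bound of the fold was above 64 for 31 of the 45 genes, but not for the other 14, the lowest bound being 36.5-fold. A candidate explanation is that part of this group depends on the state of the animals, such as age, feeding or handling, as well as on the body part. The 32 genes with at least 20 whole-body reads had a median coefficient of variation of 61.4% over the 3 whole-body libraries. In 10000 sets of 8- to 32-fold genes matched on whole-body level it was 16.9% (95% range 12.6 to 23.7%). Each matched gene was drawn on its own, so the range treats the 32 genes as independent. The range does not allow for 1 library moving many of them together, and no p-value is given. The high median rests largely on whole-body replicate 2, the highest or lowest library for 27 of the 32 genes where chance gives 21.3. Without replicate 2 the median was 20.5%, against a matched upper limit of 20.2%. It was 81.3% without replicate 1 and 40.5% without replicate 3. RNA from animals of another stage or pool, and a library-specific fault in replicate 2 or in the only proterosoma library, stay open.

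Whole-body replicate 2 differed from the other whole-body libraries in 188 genes by edgeR, a count that rests on the spread between the other 2 libraries (1 residual degree of freedom) and so on how close these are; at an unadjusted p under 0.05, replicate 3 had more genes (1095) than replicate 2 (785). The 161 genes lower in replicate 2 had a median log2 ratio to the other whole-body libraries of -0.98. Of these, 47.8% were at least 2-fold lower in the proterosoma library than in replicate 2 itself, against 44.1% of the 12228 genes tested (two-sided Fisher's exact p = 0.339 across genes, which are not independent replicates). This share used library-size scaling without a call, and choosing genes that are low in replicate 2 pushes it down. A share of called genes with TMM scaling, taken against replicates 1 and 3, was 52.8% against 32.7%. It uses the libraries that chose these genes and so is expected above the background even with no link. The 2 shares err in opposite directions, so neither decides whether these genes are linked to the body part. The values argue against a share of front-body tissue in replicate 2 low enough to give that ratio of -0.98. The 1187 genes at least 8-fold higher in the proterosoma library had a median log2 ratio of -0.02 (-0.0163, bootstrap 95% interval -0.0394 to 0.00706). They were chosen against replicates 1 and 3, which pushes this ratio up. A smaller deficit is not excluded. The 1809 genes at least 8-fold higher in the main fit held 2.74% of the reads of replicate 2, against 3.18% and 2.91% in replicates 1 and 3. With all whole-body libraries thinned to 11630954 counts, a median of 103.5 genes (45 to 183 in 10 thinnings) were still called lower in replicate 2. This argues against unequal sequencing depth as the only cause of these calls. The fall from 161 cannot tell a part played by unequal depth from the loss of power with fewer reads. A difference in culture, age or handling between the pools of females was not tested.

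The 27 genes higher in replicate 2 were mostly higher still in the proterosoma library. On library-size scaling, 19 of them (70.4%) were at least 2-fold above replicate 2 itself there, against 20.6% of the 12228 genes tested. The 27 genes were chosen by their shift in a single library and may move together, so no p-value is given. Of the 45 genes over 64-fold higher, 32 were among those tested: 9 of these (28.1%) were higher in replicate 2, against 0.221% of all tested genes, and 4 (12.5%) were lower, against 1.32%.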
